A study of Mus musculus with 9 samples.

How the data were processed

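RNA from 9 cell samples was measured on an Affymetrix mouse whole-transcript array, 1 array per sample. Per the labels, total RNA was taken up in Trizol and labelled with biotin by a terminal labelling kit for whole transcripts. The deposited table holds log2 expression values for 34760 array rows and 9 arrays. The method by which the authors made these log2 values comparable between arrays, and its software, are not given in the sources used here. The array medians over all rows lay between 6.01 and 6.23, so the values were used as deposited and no further scaling was applied. The spread of values still differed by group. The upper quartile lay at 8.237 to 8.265 on fibroblast arrays, 8.05 to 8.162 at day 3 and 8.058 to 8.091 on iPS arrays. The number of arrays, 3 per group, limits the precision.

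Rows were named through the platform's probe table. Of the 34760 rows, 21640 carried 1 gene symbol, 1321 carried several and 11799 were not in the probe table. Rows with several symbols were not used for any named gene, and unlisted rows are unnamed here, not without a gene. Of the rows with 1 symbol, 21553 matched the GRCm38.p6 gene table by gene identifier, and 0 symbols needed updating. That table served for names only, and no coordinates are given. Each of 19937 genes was represented by its row with the highest mean over the 9 arrays. For 954 genes several rows existed. Rows of 1 gene were called in opposite directions for 3 genes at day 3 against fibroblasts, 0 for iPS against day 3 and 7 for iPS against fibroblasts. Array rows do not separate an introduced copy of a gene from the cell's own transcript.

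Groups came from the sample titles and source names. For the third fibroblast array the cell type label names 3-day induced cells, whereas its title, source and passage label name fibroblasts. It was kept as a fibroblast array, and a placement with the induced arrays was run as an alternative. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Pairs of arrays held 490 to 1643 exactly equal values. Osr1 and Ppbp each read the same on all 3 day-3 arrays (7.06 and 6.99), as did Krt19 on the iPS arrays (7.73). Such ties may hide part of the spread, so the p-values of such genes may be too low.

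The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with one shared estimate of the spread and no covariate. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change was at least 2-fold. Every gene at or past 2-fold also passed the adjusted p. The highest adjusted p among them (limma, Benjamini-Hochberg) was 0.0225 at day 3 against fibroblasts, 0.00923 for iPS against day 3 and 0.00966 for iPS against fibroblasts. The fold requirement alone therefore set the numbers of called genes. For the same reason, counts adjusted over the list alone equalled those over all genes in each of the 120 list tests, and add no separate evidence. The position of each day-3 array between the fibroblast and iPS means was its projection on the line joining the group means, 0 at the fibroblast mean and 1 at the iPS mean, over the genes called between iPS and fibroblasts.

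Before the data were examined, 40 gene lists were fixed: the reprogramming factors, pluripotency, early reprogramming markers, fibroblast and mesenchymal genes, the TGF-beta response, extracellular matrix, epithelial genes, DNA methylation and demethylation, Polycomb and histone modifiers, chromatin remodelling, S phase, G2 and mitosis, the p53 pathway, MYC targets and ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon response, inflammatory cytokines, LIF, BMP and WNT signalling, germline, the 2-cell stage, imprinted, Hox, immediate early and heat shock genes, X and Y chromosome genes, and markers of primitive endoderm, trophoblast, early mesoderm, neural, Schwann, macrophage, endothelial, skeletal muscle, smooth muscle, adipocyte, chondrocyte, keratinocyte, erythroid and hepatocyte cells. Each list was tested in each comparison with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the members move on balance one way without comparing them with other genes. Benjamini-Hochberg adjustment ran over the 120 list tests. With the preset correlation 52 list tests passed, with an estimated correlation 0 passed, and with fry 92 passed.

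Genes are named by a rule set in advance: per comparison, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, without clone or predicted names; the 10 genes furthest above and below both other groups at day 3; the reprogramming factors with Pou5f1 and Nanog; and list members. The test was checked on simulated data for the real genes. With 200 of 19937 genes changed, 99% of those set at a log2 change of 1.5 and 100% of those set at 2 were recovered at day 3 against fibroblasts, with 1 false call. The simulated noise was independent between genes and arrays, and the changes set lay past the 2-fold line. The check therefore gives no error rate for the real calls. Alternatives covered the scaling between arrays, filters on dim genes, the choice of rows, the spread model, array weights, the replicate number as a block, the fold requirement and each array left out. Leaving out small RNA genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.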

Results

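The series followed mouse fibroblasts on their way to induced pluripotent stem (iPS) cells in a secondary reprogramming system. The fibroblasts were derived from mice made with iPS cells that carry doxycycline-inducible Tet1, Sox2, Klf4 and c-Myc (TSKM). The Oct4 gene Pou5f1 was not among the introduced factors. There were 3 groups of 3 arrays each: fibroblasts at passage 4, the same kind of cells after 3 days of doxycycline (TSKM-3D, called day 3 here), and an iPS line at passages 10 to 15. The design asks how expression changed over the main stages of reprogramming. At induction the medium was also changed from feeder medium to embryonic stem cell medium with LIF, so the day-3 comparison covers both changes. The iPS cells grew on mitomycin-treated mouse embryonic feeder cells, which were removed before collection by plating for 0.5 h.

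Array values were closest within groups. Across genes, which are not independent replicates, Pearson correlations ranged from 0.9952 to 0.9965 among fibroblast arrays, 0.9831 to 0.9907 among day-3 arrays and 0.9891 to 0.9911 among iPS arrays. They were 0.9526 to 0.9586 between fibroblasts and day 3, 0.9301 to 0.9319 between day 3 and iPS, and 0.908 to 0.9121 between fibroblasts and iPS. The median gene's SD was 0.07 in fibroblasts, 0.13 at day 3 and 0.11 in iPS cells on the log2 scale (n = 3 each).

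The introduced factors and their partners were looked at first. At day 3 Sox2 was 2.63-fold above the fibroblast level (log2 difference 1.39 ± 0.09 SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 1.36e-07) and Myc was 3.03-fold above it (1.60 ± 0.08; adjusted p = 1.95e-08). Klf4 differed by 0.04 ± 0.09 (adjusted p = 0.708). Tet1, a 5-methylcytosine oxidase, went against the label of these arrays as 3-day induced cells: its level fell by 1.13 on the log2 scale (SE 0.07), from 8.10 to 6.97 (limma, Benjamini-Hochberg adjusted p = 1.79e-07). After quantile normalization the difference was -0.997 ± 0.069, just inside the 2-fold line, and Tet1 was then not called, nor was it with the mean of its rows or when tested against 2-fold. Pou5f1 rose 3.6-fold (1.85 ± 0.12; adjusted p = 2.35e-07) although it was not introduced, and Nanog differed by -0.11 ± 0.10. In iPS cells all 6 genes except Myc were above their day-3 level, by 3.57 for Tet1, 4.98 for Sox2, 1.43 for Klf4, 4.71 for Pou5f1 and 6.72 for Nanog. Myc fell by 2.42 between day 3 and iPS. Of the 5 listed factors, counting Pou5f1, 3 were higher and 1 lower at day 3 (camera, Benjamini-Hochberg adjusted p = 0.109; adjusted p = 0.379 with an estimated correlation).

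**Figure D1:**
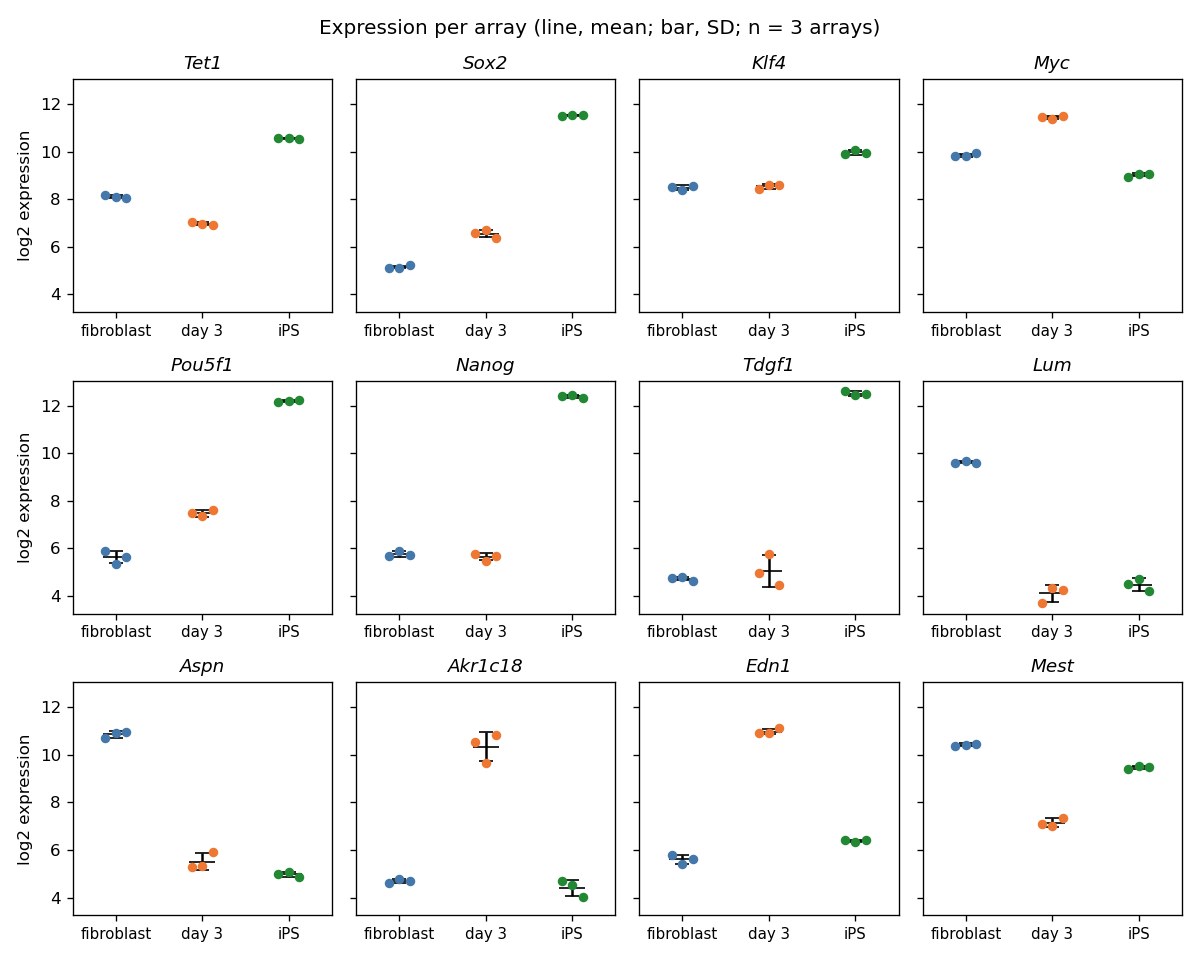
Log2 expression of 12 genes on each of the 9 arrays (points), with the group mean and SD (n = 3 arrays per group). Tet1 dips from 8.10 to 6.97 at day 3, Nanog stays near 5.7 until the iPS stage, and Akr1c18 is high only at day 3.

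Between fibroblasts and day 3, loss was more frequent than gain: 648 genes were higher and 1511 lower (limma, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), 10.8% of 19937 genes. Over all array rows, unnamed ones included, 1420 were higher and 2165 lower. The largest rises in log2 value were in Akr1c18, an aldo-keto reductase, at 5.63 ± 0.25 SE (4.72 in fibroblasts and 10.35 at day 3, n = 3 per group; adjusted p = 1.09e-08), the aldehyde dehydrogenase Aldh1a7 at 5.48 ± 0.10 (4.24 and 9.72), Usp17ld at 5.41, the vasoconstrictor peptide gene Edn1 at 5.37, Sostdc1 at 4.96, Gna14 at 4.27, Aldh1a1 at 3.94, Cd200r2 at 3.79, the keratin gene Krt19 at 3.61 and Tspan13 at 3.59. The 3 largest falls were in Lum at -5.51, Aspn at -5.35 and Serpina3n at -5.25 (limma, Benjamini-Hochberg adjusted p at most 1.03e-09). The next were Srpx2 at -4.91, Tnmd at -4.81, the small nucleolar RNA gene Snora21 at -4.76 (-0.44 on its other row), Lrrc17 at -4.60, Thbs4 at -4.46, the proteoglycan gene Dcn at -4.44 and the growth factor gene Igf2 at -4.37. Several of the lower readings were dim, since the lower quartile of the array rows lay at 4.54 to 4.55 in fibroblasts and 4.61 to 4.73 at day 3, and signal over background was not measured, so the size and order of these changes are uncertain. Over all genes, the 3 arrays of one group lay outside the range of the other for 53.1%, where chance gives 10%. Placing the third fibroblast array with the induced arrays, as its cell type label would have it, left 0 called genes, with 5359 at an unadjusted p under 0.05. That array correlated at 0.9952 and 0.9965 with the other fibroblast arrays and at 0.9531 to 0.9586 with the day-3 arrays. It read 9.60 for Lum, against 3.71 to 4.36 on the day-3 arrays, and 4.71 for Akr1c18, against 9.68 to 10.81, so that placement mixes unlike arrays in 1 group and raises its spread.

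Of 36 measured fibroblast and mesenchymal genes 18 were lower, 1 higher and 17 neither (camera, Benjamini-Hochberg adjusted p = 1.43e-09; adjusted p = 0.108 with an estimated correlation). The surface marker gene Thy1 changed by -2.41 and the transcription factor genes Snai1, Snai2 and Osr1 by -2.69, -2.81 and -4.32, whereas Twist1 rose by 1.24. Of 47 matrix genes 15 were lower and 2 higher (camera, Benjamini-Hochberg adjusted p = 0.00488; adjusted p = 0.483 with an estimated correlation). Ogn changed by -2.90 and Col6a3 by -2.32, but Col1a1 stood at 12.20 in fibroblasts and 12.31 at day 3, and Nid2 rose by 1.30. Some macrophage markers were lower as well. Of 17, 6 were lower and 0 higher, with 9.18 against 5.17 for Lyz2, 8.22 against 5.31 for Cd53 and 7.24 against 5.62 for C1qb (camera, Benjamini-Hochberg adjusted p = 7.56e-05; adjusted p = 0.146 with an estimated correlation). A block of 16 bright unnamed rows with the lowest row numbers, chosen after the data were seen, also shifted between the same arrays, with a median log2 difference of 1.64.

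Of 42 MYC targets and ribosome biogenesis genes 9 were higher and 0 lower (camera, Benjamini-Hochberg adjusted p = 2.07e-07; adjusted p = 0.155 with an estimated correlation), among them Tsr1 (1.70 ± 0.07), Mrto4 (1.60 ± 0.08, although a second row of this gene changed by -0.84) and Nop58 (1.56 ± 0.09). Of 49 G2 and mitosis genes 10 were lower and 2 higher (adjusted p = 1.28e-05; adjusted p = 0.465 with an estimated correlation), with Mki67 at -1.47 and Cdk1 at -1.23, and Lbr higher by 1.32. Of 44 S phase genes 6 were lower and 0 higher (camera, Benjamini-Hochberg adjusted p = 0.136), led by E2f8 at -1.87. Of 33 p53 pathway and senescence genes 10 were higher and 3 lower (adjusted p = 0.00293; adjusted p = 0.407 with an estimated correlation). The death receptor gene Fas rose by 2.47, Pmaip1 by 2.53 and Cdkn2a, which encodes the p16 and p19 growth inhibitors, by 1.51.

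Pluripotency and epithelial genes were mostly not called at day 3. Of 36 pluripotency genes 3 were higher (Pou5f1, Sox2 and Klf5, the last by 1.81 ± 0.07) and 33 were neither (camera, Benjamini-Hochberg adjusted p = 0.0537). Of 13 early reprogramming markers 0 were called and 5 reached an unadjusted p under 0.05 in limma (camera, Benjamini-Hochberg adjusted p = 0.504). Of 31 epithelial genes Krt19 and Perp were higher and Cdh3 lower (camera, Benjamini-Hochberg adjusted p = 0.00488; adjusted p = 0.465 with an estimated correlation), while Cdh1, E-cadherin, differed by 0.34 ± 0.10 and Epcam by 0.34 ± 0.09. The TGF-beta response list was split, 5 higher and 5 lower of 25, with Smad7 at 1.73 and Skil at 1.70. Its median was -0.04 and its mean 0.07, with camera giving the direction down and fry up (camera, Benjamini-Hochberg adjusted p = 0.595).

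Between day 3 and iPS cells, 1292 genes were higher and 1709 lower (limma, Benjamini-Hochberg, at least 2-fold), 15.1% of genes. Over all array rows, unnamed ones included, the balance was reversed, with 2430 higher and 2144 lower. Pluripotency genes led the rises. In log2 value Tdgf1 rose by 7.43 ± 0.24 SE (5.07 at day 3 and 12.50 in iPS cells, n = 3 per group; adjusted p = 5.35e-10), Dppa5a by 7.30, Nr0b1 by 6.87, the transcription factor gene Nanog by 6.72 and Fbxo15 by 6.48. Their day-3 readings, 3.87 (Fbxo15) to 5.66 (Nanog), were dim, so the size and order of these rises are uncertain. Among the 10 largest falls were genes that had risen at day 3 (Akr1c18 at -5.92, Aldh1a7 at -5.44 and the growth factor gene Ereg at -5.29) and the adhesion gene Vcam1 at -4.83. Groups did not overlap for 49.5% of genes, where chance gives 10%.

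Of 36 pluripotency genes 33 were higher in iPS cells than at day 3 and 0 lower (camera, Benjamini-Hochberg adjusted p = 3.2e-27; adjusted p = 0.108 with an estimated correlation). They included Esrrb (5.54 ± 0.13), Sall4 (4.65 ± 0.16) and Zfp42 (3.70 ± 0.14). Of 13 early markers, several of which are also in the pluripotency list, 12 were higher (adjusted p = 2.63e-11; adjusted p = 0.146 with an estimated correlation). Of 31 epithelial genes 17 were higher and 2 lower, Cdh1 by 4.89 and Epcam by 4.54 (camera, Benjamini-Hochberg adjusted p = 2.03e-09; adjusted p = 0.155 with an estimated correlation). The 2 that fell, Krt19 and Perp, were those that had risen at day 3. S phase genes rose nearly as a block, 37 of 44 higher and 0 lower (adjusted p = 2.68e-20; adjusted p = 0.14 with an estimated correlation), with Mcm5 at 2.32 ± 0.07 and Pold3 at 2.09 ± 0.13. Of 49 G2 and mitosis genes 19 were higher and 0 lower (camera, Benjamini-Hochberg adjusted p = 6.84e-14; adjusted p = 0.212 with an estimated correlation). No MYC target among 42 was called, 34 reached an unadjusted p under 0.05 in limma, and camera gave an adjusted p of 4.57e-06 (adjusted p = 0.192 with an estimated correlation).

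Between day 3 and iPS, chromatin lists differed in their counts. Of 33 DNA methylation and demethylation genes 11 were higher and 4 lower (camera, Benjamini-Hochberg adjusted p = 0.0329; adjusted p = 0.302 with an estimated correlation). The methyltransferase cofactor gene Dnmt3l rose by 5.62, the methyltransferase gene Dnmt3b by 2.88 and Tet2 by 2.05, and Gadd45g fell by 3.09. Of 44 Polycomb and histone modifier genes 15 were higher and 1 lower (adjusted p = 4.97e-06; adjusted p = 0.229 with an estimated correlation). Jarid2 rose by 3.00 and Mtf2 by 2.90, both accessory factors of Polycomb repressive complexes, and Bmi1 fell by 1.62. At day 3 against fibroblasts 0 Polycomb genes had been called, with 30 at an unadjusted p under 0.05 in limma, and 3 DNA methylation genes had been higher and 2 lower. Of 33 chromatin remodelling genes 3 were higher and 3 lower between day 3 and iPS (adjusted p = 0.955), with Actl6a at 1.68 and Smarca2 at -2.55.

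Further fibroblast genes were lower in iPS cells than at day 3. Of 36 fibroblast and mesenchymal genes 23 were lower and 1, Dcn, higher (camera, Benjamini-Hochberg adjusted p = 2.86e-11; adjusted p = 0.108 with an estimated correlation). Twist1 changed by -3.08 and Thy1 by -1.70. Of 25 TGF-beta response genes 21 were lower and 0 higher (adjusted p = 1.17e-14; adjusted p = 0.132 with an estimated correlation), with Tgfb3 at -3.37. Of 47 matrix genes 26 were lower and 1 higher (adjusted p = 7.24e-11; adjusted p = 0.155 with an estimated correlation). The iPS arrays still read 11.47 for Col1a1 and 8.53 for Dcn, and this group alone was grown on feeder fibroblasts. Of 33 p53 pathway genes 15 were lower and 0 higher (camera, Benjamini-Hochberg adjusted p = 8.23e-07; adjusted p = 0.185 with an estimated correlation), with Rb1 at -3.47 and Fas at -3.45.

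**Figure D2:**
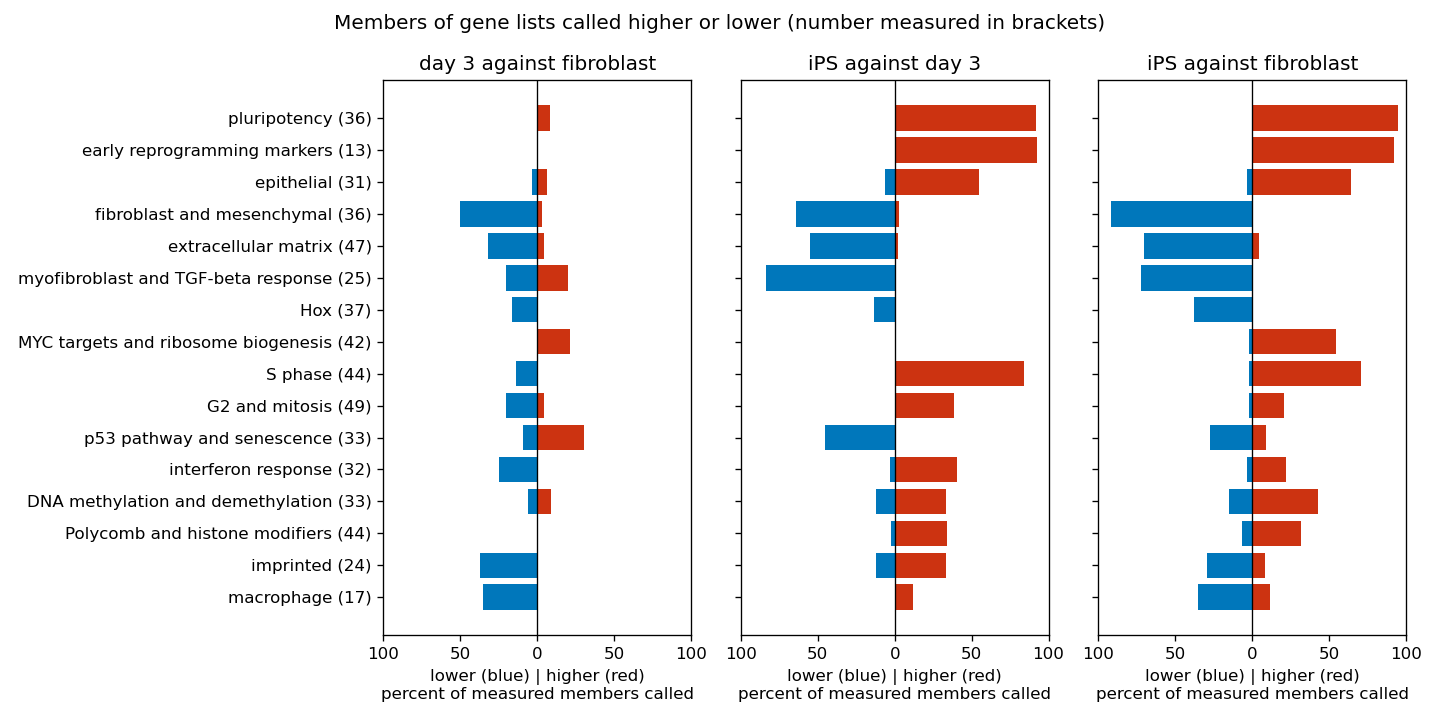
Percent of the measured members of 16 gene lists called higher (to the right) or lower (to the left) in each of the 3 comparisons. Of 36 pluripotency genes 3 were higher at day 3 and 33 between day 3 and iPS, while fibroblast and mesenchymal genes fell in both steps, 18 and then 23 of 36.

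Over the whole course, iPS cells against fibroblasts, 1522 genes were higher and 2761 lower (limma, Benjamini-Hochberg, at least 2-fold), 21.5% of genes. Over all array rows 3366 were higher and 3587 lower, and with array medians set equal 1224 genes were higher and 3267 lower. From dim fibroblast readings Tdgf1 rose by 7.77 ± 0.24 SE in log2 value (n = 3 per group; adjusted p = 2.14e-10), Dppa5a by 7.46, Bex1 by 7.21 and Nr0b1 by 7.15. The largest falls were in Aspn (-5.88), Osr1 (-5.63) and the chemokine gene Ppbp (-5.45). Their iPS readings, 4.98, 5.75 and 5.14, lay below the iPS array medians of 6.20 to 6.23, so the size and order of these falls are uncertain. Of the 36 pluripotency genes 34 were higher and 0 lower (camera, Benjamini-Hochberg adjusted p = 1.31e-22; adjusted p = 0.108 with an estimated correlation), and of the 36 fibroblast and mesenchymal genes 33 were lower and 0 higher (adjusted p = 7.26e-18; adjusted p = 0.077 with an estimated correlation). Of 42 MYC targets 23 were higher and 1 lower over the whole course (adjusted p = 1.41e-10; adjusted p = 0.146 with an estimated correlation), with Nop58 higher in both the day-3 and the iPS comparison with fibroblasts, by 1.56 and 1.75. Of 44 S phase genes 31 were higher and 1 lower (adjusted p = 1.07e-11; adjusted p = 0.179 with an estimated correlation). The matrix, TGF-beta response and epithelial lists had 33 lower and 2 higher of 47, 18 lower and 0 higher of 25, and 1 lower and 20 higher of 31, with Vcan at -3.68, Tgfb3 at -4.03 and Cdh1 at 5.23 (camera, Benjamini-Hochberg adjusted p = 8.04e-14, 9.95e-08 and 1.41e-10; adjusted p = 0.147, 0.155 and 0.155 with an estimated correlation). Of 33 DNA methylation genes 14 were higher and 5 lower, and of 44 Polycomb genes 14 were higher and 3 lower (adjusted p = 0.0259 and 0.00129; adjusted p = 0.281 and 0.407 with an estimated correlation). G2 and mitosis genes had 10 higher and 1 lower and p53 pathway genes 3 higher and 9 lower (adjusted p = 0.0121 and 0.012; adjusted p = 0.706 and 0.465 with an estimated correlation). Beside these lists, 6 macrophage markers were lower and 2 higher (adjusted p = 0.118), Lyz2 at -3.14, and the 16 bright low-numbered rows differed by a median of 1.89 between the fibroblast and iPS arrays. Groups did not overlap for 65% of genes, where chance gives 10%. Setting the array medians equal would move the median gene from 0.05 to -0.12 in this comparison and from -0.01 to -0.13 in the day 3 to iPS comparison.

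A larger share of the losses than of the gains was already called at day 3. Of the 2761 genes lower in iPS cells than in fibroblasts, 1079 (39.1%) were already lower at day 3, and of the 1522 genes higher, 251 (16.5%) were already higher at day 3. Lum, Serpina3n and Snai1 fell at day 3 with no further call, Meox2 and Cdh2 were called only later (-3.52 and -3.55), and Thy1 and Osr1 fell in both steps. Among gains, Usp17ld was called at day 3 and kept its level (10.81, then 11.21), while Nanog, Esrrb and Cdh1 were called higher only later. Genes called higher in both steps numbered 36, Bex1 and Slc2a3 among them, and 226 were called lower in both. Independent lists, which ignore the shared day-3 arrays, would share 42.0 and 129.5, so the 36 are no excess. A further 28 of the genes finally higher had been lower at day 3, and 76 of those finally lower had been higher. On the line between the fibroblast and iPS means, day-3 arrays stood at 0.195 ± 0.0051 (SD, n = 3) over genes higher in iPS and at 0.438 ± 0.028 over genes lower in iPS. Both comparisons share the fibroblast arrays. Independent lists of these sizes would share 49.5 higher and 209 lower genes. Across genes the 2 sets of log2 differences correlated at 0.548, against 0.499 simulated with no effect, and their covariance was 0.358 against 0.0071. Independent noise on the shared arrays thus gave little of the covariance. A split of the 3 fibroblast arrays would leave 1 array on one side and was not made, so its part in the excess overlap was not counted. The simulation does not cover a step common to the 3 fibroblast arrays, which could add to the overlap.

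Some genes were highest or lowest at day 3. Genes called above both other groups at day 3 numbered 291, and 196 lay below both. Independent lists would give 55.6 and 97.9. Akr1c18, Aldh1a7, Sostdc1, Edn1, Aldh1a1 and Ereg were among the highest, with Aldh1a1 at 5.22 in fibroblasts, 9.16 at day 3 and 5.12 in iPS cells. Among the lowest were the sodium pump subunit gene Atp1b1 (8.70, 5.71 and 9.94), the imprinted gene Mest (10.42, 7.16 and 9.47) and the interferon-induced Ifi27 (9.99, 7.91 and 10.09). For these 3 the difference exceeded the spread in both steps (limma, Benjamini-Hochberg adjusted p at most 2.86e-08). Both calls use the same day-3 arrays, and across genes the 2 steps correlated at -0.134, against -0.496 simulated with no effect. Their covariance was -0.0737, against -0.0070 simulated. In 20 simulations of these shared arrays with no group differences, the highest count of such genes was 0 in each direction. The simulated noise was independent between genes and arrays, so a step common to the 3 day-3 arrays is not covered.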

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

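The tests of the low-numbered rows, of Tet1 and of the matrix genes were chosen only after those results were seen. The tests on other groupings of the arrays were set before.

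Array rows without a gene name entered no comparison between named genes, and many of them differed between groups. Of 11799 such rows, 594 were called higher and 457 lower at day 3 than in fibroblasts, 1474 higher and 593 lower in iPS cells than in fibroblasts, and 892 higher and 284 lower in iPS cells than at day 3 (limma, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold). Within them, 16 bright rows of a block of 21 with the lowest row numbers were brighter on the day-3 arrays than on the fibroblast arrays by a median of 1.64 on the log2 scale. On these rows the day-3 and iPS arrays differed by a median of 0.19, with 0 of 16 called.

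This shift is what fibroblast arrays labelled or hybridised apart from the other 6 could give, with array medians of those rows of 8.25 to 8.31 in fibroblasts and 10.2 to 10.6 on the other arrays. Such a step sets the fibroblast arrays apart and leaves day-3 and iPS arrays alike. Yet 22.6% of the genes called at day 3, Akr1c18 among them, were called the opposite way between day 3 and iPS. These were 291 and 196 genes, against 55.6 and 97.9 from independent lists, which ignore the shared day-3 arrays. Such a step cannot give that later difference. The later comparison leaves out the fibroblast arrays, so it does not decide what gave the day-3 change of those genes. For all genes called at day 3, whether or not they kept the change, such a step cannot be told apart from induction, because it would coincide with the groups. Of 1194 olfactory and vomeronasal receptor genes 0 were called at day 3 (194 at an unadjusted p under 0.05 in limma), but neither cell type is known to use them, so they do not decide it for expressed genes. A change with induction is the biological alternative, and nothing tested it for these rows.

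Tet1 is one of the introduced factors, yet it was lower on the arrays labelled as 3-day induced. For cells that were not induced, or arrays exchanged between both groups, the test made decides nothing. Sox2 rose by 1.39 and Myc by 1.60, but Pou5f1, which was not introduced, rose by 1.85. Klf4, which was introduced, differed by 0.04. A rise need not come from an introduced copy, so the criterion first written was wrong, and a lack of induction stays open. Other values argue against an exchange of the 2 groups. The day-3 arrays correlated at 0.9301 to 0.9319 with the iPS arrays, and the fibroblast arrays at 0.908 to 0.9121. Of 36 fibroblast and mesenchymal genes, 18 were lower and 1 higher on the arrays labelled day 3. By the criterion first written for scaling, loss of the call, scaling could account for the called fall of Tet1. Quantile normalization took Tet1 from -1.13 ± 0.07 SE to -0.997 ± 0.069 (adjusted p = 2.54e-07, limma with Benjamini-Hochberg), which missed the 2-fold line. That line was a poor choice, and a second test, set after the first was seen, found the fall still 14.5 standard errors from 0, so scaling does not remove it. A candidate explanation for the lack of a rise stays open, that the 3 Tet1 rows read sequence outside the introduced copy. These rows changed by -1.23, -0.46 and -1.13, with none called higher. Since their positions were not used here, a true lack of induced Tet1 cannot be told apart from this candidate. Neither would by itself account for the fall. A lower level of the cell's own transcript could give it, and so could fibroblast arrays labelled or hybridised apart. These cannot be told apart here.

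Collagen and other matrix genes stayed bright on the iPS arrays, where Col1a1 kept 60% of its fibroblast level. Fibroblast arrays labelled or hybridised apart could raise such shares by reading low, and the test made of this decides nothing: 6 of 6 collagens (Col1a2, Col3a1, Col5a1, Col5a2, Col4a1 and Col4a2) were called lower in iPS cells than at day 3 and Col1a1 was not (12.31 and 11.47), but that comparison leaves out the fibroblast arrays, so the criterion first written was wrong. RNA of feeder fibroblasts is a candidate source, although the feeders were removed by plating. Over the 67 genes of the fibroblast, matrix and TGF-beta lists with a fibroblast mean of at least 10, the level kept in iPS cells ranged from 2.01% (Osr1) to 111% (Ccn2) with a median of 16.2%, and Thy1 kept 5.78% and S100a4 2.85%. One share of cells like the fibroblasts studied would keep all at 1 level, but the feeders' own profile is unknown and expression by iPS cells is possible, so none of these can be excluded and they cannot be told apart.

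On other groupings of the arrays, 3 against 3 gives 10 splits, too few for a share under 0.05. In each comparison only 1 of the 10 splits, the real one, called any gene. The real counts were 2159, 3001 and 4283, and the highest of the other splits was 0 each time (limma), with 70 to 651, 221 to 1125 and 63 to 101 genes at an unadjusted p under 0.05. For the genes highest or lowest at day 3, only 1 of 100 splits of the 9 arrays, the real one, gave as many as 487. Splits that mix the groups put the group differences into the spread, so they could call few genes. The share therefore does not exclude chance. The highest other split gave 469, and it kept the 3 day-3 arrays together and mixed fibroblast and iPS arrays. Any middle group has many such genes: 1330 lay beyond both others in fibroblasts and 2158 in iPS cells.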

How the results depend on the processing

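All alternatives were set before the data were examined except leaving out small RNA genes, which was added afterwards. No position and no called named gene changed direction, while Klf4 at day 3, which was not called, ranged from -0.037 to 0.190. Of 274 alternative counts, percentages and positions, 228 stayed the same by a rule set for each kind. A count had to lie within 1.5 times the reported value and a position within 1 SD. A percentage of gains or losses had to lie within the 95% binomial interval of the reported one. The cause of each larger move was not tested unless the setting itself gives it. Placing the third fibroblast array with the day-3 arrays, as its cell type label has it, left 0 genes higher and 0 lower between those groups (5359 at an unadjusted p under 0.05, lowest adjusted p 0.165 in limma), hence 0 highest and 0 lowest at day 3, 0% of gains and 0% of losses by day 3, and positions of 0.139 and 0.325. It also ended 42 of the 45 named gene calls that weakened anywhere; the other 3 were Tet1 at day 3. With the mean of all rows of a gene, 1 of the 2159 calls at day 3 against fibroblasts reversed. Using all rows gave 1420 higher and 2165 lower, 2430 and 2144, and 3366 and 3587 in the 3 comparisons in turn, so that the balance was reversed between day 3 and iPS and nearly even between fibroblasts and iPS, with 330 lowest at day 3, 22.1% of gains by day 3 and positions of 0.271 and 0.474, where unnamed rows, rows with several symbols and further rows of named genes were added at once. Without the fold requirement 3832 genes were higher and 5054 lower at day 3 than in fibroblasts, 4453 and 4635 between day 3 and iPS, 5091 and 5792 between fibroblasts and iPS, 1489 were highest and 1706 lowest at day 3, and 43% of gains and 64.7% of losses had come by day 3, with a position of 0.224 for gains. Testing against 2-fold (treat) left 343 and 797, 803 and 1128, and 997 higher between fibroblasts and iPS, with 159 highest and 75 lowest at day 3, 12% of gains, 29.1% of losses and a position of 0.185. Quantile normalization gave 19.7% of gains and 34.9% of losses by day 3 and positions of 0.212 and 0.395. With it 803 genes were higher and 1252 lower at day 3 than in fibroblasts, against 648 and 1511 without it. Setting array medians equal gave 1224 genes higher and 3267 lower between fibroblasts and iPS and a position of 0.176 for gains. Without the dimmest 25% of genes it was 0.2003, without the dimmest 50% it was 0.245, with 21.8% of gains and 36.3% of losses by day 3, and without small RNA genes it was 0.186.

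Because the 2-fold line alone set the calls, settings that change only the spread could hardly move them, and their sameness says little about stability. With the replicate block 648 and 1511 genes were called at day 3, as without it, and 8769 instead of 8886 passed the adjusted p alone. The same number did not pair the arrays: deviations from the group means correlated at -0.0979 to 0.0618 for shared numbers and -0.132 to 0.13 for others. An intensity trend gave the same counts, with 8964 past the adjusted p alone. Array weights ranged from 0.2 to 16.5, and their estimation stopped before its tolerance was reached, so that setting is of little use. Leaving out each array in turn moved no count by over 1.5 times: genes higher at day 3 ranged from 598 to 734. Of the list tests, an estimated correlation ended all 52 that had passed and fry added 40. With an estimated correlation even pluripotency genes between day 3 and iPS, 33 of 36 higher and 0 lower, did not pass (camera, Benjamini-Hochberg adjusted p = 0.108). A list not passing at that setting therefore does not show that its members did not shift. An offset before the logarithm was not run, since the table is already log2. Signal over background cannot be judged from this table, which limits what can be said of dim genes.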

Other observations

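The families of small RNA genes below were chosen after the data were seen, and the lists were not.

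Of 24 imprinted genes 9 were lower and 0 higher at day 3 than in fibroblasts (camera, Benjamini-Hochberg adjusted p = 0.00172; adjusted p = 0.146 with an estimated correlation), then 8 were higher and 3 lower between day 3 and iPS (adjusted p = 0.0858), and 2 higher and 7 lower over the whole course (adjusted p = 0.211). Meg3 changed by -1.71 and then 2.09, Mest by -3.26 and then 2.31, and Dlk1 by -3.03 with no later call (0.08). Of 32 interferon response genes 8 were lower at day 3 (adjusted p = 0.0409; adjusted p = 0.419 with an estimated correlation), 13 were higher and 1 lower between day 3 and iPS (adjusted p = 5.97e-05; adjusted p = 0.155 with an estimated correlation), and 7 higher and 1 lower over the whole course (adjusted p = 0.0271; adjusted p = 0.39 with an estimated correlation). The signalling gene Stat2 changed by -1.80 and then 1.99, and Rtp4 by -1.11 and then 3.01. Of 37 Hox genes 6 were lower at day 3, 5 between day 3 and iPS and 14 over the whole course, with 0 higher each time (camera, Benjamini-Hochberg adjusted p = 0.00293, 0.000279 and 4.57e-06; adjusted p = 0.192, 0.155 and 0.132 with an estimated correlation). Hoxc6, at -1.16 and -1.49, was the only one called in both steps. Germline genes, 32 in all, showed 1, 14 and 15 higher and 0, 2 and 1 lower in the 3 comparisons in turn (adjusted p = 0.0884, 1.89e-07 and 7.87e-08; adjusted p = 0.132 with an estimated correlation in both later ones), with Tdrd12 at 4.78 and the receptor gene Kit at 3.96 between day 3 and iPS. Of 11 genes of the 2-cell stage 0 were called at day 3 (4 at an unadjusted p under 0.05 in limma), 5 were higher between day 3 and iPS and 6 over the whole course, with 0 lower (camera, Benjamini-Hochberg adjusted p = 0.13, 0.00046 and 0.00018; adjusted p = 0.22 and 0.193 with an estimated correlation in the last 2).

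Members of the signalling and stress lists went both ways. Of 29 immediate early and heat shock genes 5 were higher and 4 lower at day 3, 1 and 7 between day 3 and iPS, and 5 and 6 over the whole course (camera, Benjamini-Hochberg adjusted p = 0.0524, 0.254 and 0.68). Egr2 changed by 2.41 and then -2.33, and Nr4a1 by 2.35 and then -2.22. Of 36 LIF, BMP and WNT genes 7, 2 and 5 were higher and 11, 12 and 16 lower in turn (adjusted p = 0.639, 0.00175 and 0.0145; adjusted p = 0.192 and 0.297 with an estimated correlation in the last 2), with the BMP target Id4 at 2.41 and then -1.42, and the MAP kinase phosphatase gene Dusp6 at 2.15 and then -2.11. Of 29 inflammatory genes 4, 3 and 3 were higher and 5, 8 and 9 lower (adjusted p = 0.858, 0.0616 and 0.481), among them Tnfaip3 at 2.56 and then -2.01. Of 22 glycolysis genes 3, 3 and 5 were higher and 2 lower each time (adjusted p = 0.573, 0.0932 and 0.344), and the glucose transporter gene Slc2a3 rose in both steps, by 2.46 and 3.35. Of 47 oxidative phosphorylation genes 2, 2 and 4 were higher and 4, 0 and 7 lower (adjusted p = 0.592, 0.777 and 0.481). Of 20 cholesterol synthesis genes 1, 1 and 0 were higher and 1, 5 and 7 lower (adjusted p = 0.986, 0.000141 and 0.0329; adjusted p = 0.132 and 0.227 with an estimated correlation in the last 2), with Hsd17b7 at -2.31 between day 3 and iPS. Of 33 chromatin remodelling genes 1 was higher and 3 lower at day 3, and 2 higher and 8 lower over the whole course (adjusted p = 0.135 and 0.354).

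Lists of markers of other cell types seldom passed with camera. With fry more of them passed. At day 3 these were neural, macrophage, smooth muscle, adipocyte and chondrocyte markers, lower on balance, and hepatocyte markers, higher (fry, Benjamini-Hochberg adjusted p at most 0.0351). Between day 3 and iPS, trophoblast and keratinocyte markers were among those that passed, both higher (fry, adjusted p = 0.00138 and 0.00763). In the 3 comparisons in turn, higher and lower calls were 0 and 2, 0 and 1, and 1 and 2 for primitive endoderm, 0 and 0, 2 and 0, and 2 and 0 for trophoblast (camera adjusted p = 0.0406 and 0.0408 in the last 2; adjusted p = 0.483 with an estimated correlation), 0 and 3, 2 and 1, and 1 and 2 for neural, 0 and 0, 1 and 1, and 1 and 1 for Schwann, and 0 and 1, 2 and 0, and 2 and 1 for skeletal muscle (over the whole course adjusted p = 0.0404; adjusted p = 0.592 with an estimated correlation). Smooth muscle and adipocyte markers had 2 lower at day 3 and 2 over the whole course each. Chondrocyte had 1 lower at day 3 and 1 higher later, keratinocyte 1 higher later (Sfn), and hepatocyte 2 higher at day 3 (Apoa2 and Ahsg). Early mesoderm, endothelial and erythroid markers had 0 calls, with 3, 3 and 0 members at an unadjusted p under 0.05 at day 3 in limma, 0, 4 and 0 between day 3 and iPS, and 4, 8 and 0 over the whole course. Of 4 X and Y chromosome genes 1 was higher and 1 lower between day 3 and iPS. Xist rose by 1.11 in that step, but 0 of the 4 were called higher with array medians set equal. At day 3 Kdm5d and Uty were lower (-1.27 and -1.15) and Eif2s3y was higher (1.54). Macrophage markers had 2 higher between day 3 and iPS, Laptm5 and Cd68 (adjusted p = 0.0329; adjusted p = 0.328 with an estimated correlation).

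Of 20 H/ACA small nucleolar RNA genes 7 were lower and 2 higher at day 3, and 17 higher and 0 lower between day 3 and iPS, with medians of -0.77 and 1.74, and the direction of the median was the same with array medians set equal (-0.82 and 1.62) and under quantile normalization (-0.63 and 1.77). Of 31 C/D small nucleolar RNA genes 2 were higher and 5 lower at day 3, with a median of 0.05. Between day 3 and iPS 22 were higher and 0 lower, with a median of 1.20, and 17 were higher with array medians set equal. Of 291 microRNA genes 12 were higher and 5 lower at day 3, 2 and 8 between day 3 and iPS, and 19 and 8 over the whole course.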
